A study of Homo sapiens with 61 samples.

How the data were processed

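The samples are total RNA of cultured normal human cells, labelled with biotin-11-UTP and hybridised singly to 61 one-colour arrays. The deposited values are one linear brightness per probe, in the unit intensity, for 19664 probes. The authors' background correction, scaling, scanner and software are not given in the sources used here. The array medians lie between 1.00 and 1.02, so each array had been scaled to a median near 1, and 997 values lie below 0, so a background had been subtracted. The table holds 12367 exact zeros, 1.03% of the values. Above the lowest brightness class, exact zeros make up 0.572% to 0.656% of the values at every brightness, so they were read as spots without a value and treated as missing. Zeros of a tested gene fell on arrays of one cell type more often than chance, in 138 pairs, against at most 75 in 200 shuffles of the types and 83 within array sets. That could come from cultures or from arrays handled together, so single zeros may still stand for absent RNA, and 16 genes have 3 or more in one type. The number of arrays and the signal over the floor of each array limit the precision. The floor (the 10th percentile of an array) lies between 0.0787 and 0.132, and the brightest spot between 118 and 337. A median of 16 spots per array lie within 5% of its brightest spot, so differences between very bright genes can be compressed.

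Cell types, lineages and vessel classes were taken from the sample titles. The pooled dermal fibroblasts are titled neonatal, and no other title gives an age or pooling. The 31 cell types form 5 lineages: endothelial (16 arrays of 6 types), smooth muscle (26 of 15), fibroblast (7 of 3), stromal (6 of 4) and epithelial (6 of 3). Smooth muscle, fibroblast and stromal cultures together, 39 arrays of 22 types, are called mesenchymal. The title numbers count the replicates of a type. Nothing in the labels says whether replicates are separate donors, separate cultures or repeated arrays, so the p-values measure only the spread between these samples.

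Probes were named from a table that pairs the array's probes with genes, and the symbols were taken through Entrez IDs from the RefSeq gene table of GRCh38.p14, used for names only. A single symbol was found for 16072 probes, 16061 of them through an Entrez ID, while 76 probes had several symbols and 3516 none. Sex-linked genes (XIST, TSIX and Y-linked genes) were removed before any test. Probes missing on more than 10% of the arrays were left out (290 probes, 74 of them zero on every array). A probe was kept when it lay above the median of its array on at least 2 arrays, which held for 12973 probes (67.0% of 19374). Each gene was represented by its brightest probe, which gave 9655 tested genes (9647 for the renal comparison), 1255 of them with at least 1 gap. Values were log2(value + 0.103), where 0.103 is the 10th percentile of the positive values and negative values were first set to 0. No further normalization was applied, since the array medians hardly differed. Differences between genes whose dimmer group lies near the array floor are limited by that floor.

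Models were fitted in the manner of limma (R 4.3.3, limma 3.58.1, statmod 1.5.0), with moderated statistics, a mean-variance trend and Benjamini-Hochberg adjusted p-values. A gene was called at an adjusted p under 0.05, and every adjusted p printed for a gene is from these limma fits. Lineage comparisons used all 61 arrays with the 5 lineage means, averaged evenly for mesenchymal cultures. Class comparisons used the 26 smooth muscle or the 16 endothelial arrays. In these fits the cell type entered as a random factor through duplicateCorrelation, with within-type correlations of 0.544, 0.381 and 0.327. The iliac and renal comparisons and the F-test among the 22 mesenchymal types came from a fit of 31 cell type means to all 61 arrays. Array similarity was Pearson's r across genes, with 100000 two-sided permutations of the type labels within lineages. For the count of nearest arrays, lineage labels were shuffled over single arrays as often. Levels are means ± SD of log2 intensity over arrays, and differences are given ± SE.

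The genes named for each comparison follow a fixed rule: the 10 called genes with the largest rise, the 10 with the largest fall, and up to 4 measured members with the largest absolute difference from each list described there. For the F-test they are the 10 HOX genes and the 10 other genes of the highest F. Genes named outside this rule were chosen after their values were seen. Since named genes were picked by size on these same arrays, counts of arrays on the stated side describe them and test nothing. The 24 gene lists are endothelial, arterial endothelial, venous and lymphatic endothelial, microvascular endothelial, smooth muscle contractile, fibroblast, collagen and matrix, simple epithelial and junction, stratified epithelial, renal tubule, skeletal myoblast, regional mesenchyme regulators, HOX paralogs 1 to 5, 6 to 8 and 9 to 13, vasoactive and hormone receptors, TGF-beta and Notch targets, proliferation, interferon response, inflammatory cytokines and adhesion, sterol and lipid synthesis, stress and immediate early, leukocyte and blood, and melanocyte and neural. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 216 list tests, with camera at an estimated correlation beside it. The lists share some members and were not pruned. List members without a usable probe, such as ACTA2, MYH11, TP63 and NR2F2, are not analysed here. The comparisons, tests, gene lists, naming rule and first group of alternatives below were chosen before the data were examined.

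Array sets were defined after the data had been seen. Some probes sit in 1 of 2 clearly separate states (a gap of at least 1 log2 unit, at least 4 arrays on each side) that cut across at least 2 lineages. Splits shared by at least 5 such probes were taken to mark array sets, which were treated as technical although no label shows it: 74 probes set 6 arrays apart and 7 probes set 27 arrays apart, which gives sets of 28, 27 and 6 arrays. The sets entered as a fixed term in an alternative model, and the comparisons were also made within each set. The first group of alternatives was quantile normalization, centring on array medians, pseudocounts at the 1st and 25th percentile, no and a stricter (75th percentile) dim-probe filter, the mean of a gene's probes, a model without trend, a robust model, a difference of at least 1 log2 unit, the title number as a block, no cell type factor, 1 mean per cell type, other arrays in the fit, and leaving out each array or cell type. Exact zeros read as 0, the array set, the array floor as a covariate, leaving out 2 doubted arrays, and similarity within a set were added after the data were seen.

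The procedure was tested on simulated data with the group sizes, spread and within-type correlation of the real table. Of genes simulated with a difference of 1 log2 unit, 85% were called for endothelial against mesenchymal cultures, 73% for epithelial against mesenchymal, 79% for smooth muscle against fibroblast, 60% for stromal against fibroblast and 80% for vascular against visceral smooth muscle. The share was 54% for arterial against venous smooth muscle, 87% for arterial against microvascular endothelial, 87% for iliac against umbilical artery and 59.6% for renal against lower genital cultures. At 2 log2 units the shares lay between 88% and 99%. False calls made up 3.4% to 9.8% of the calls, the highest for arterial against microvascular endothelial cultures, where the within-type correlation came out at 0.229 in place of 0.327. The F-test called 195 of 200 simulated genes with 9 false calls. In the simulation of vascular against visceral smooth muscle, camera found the shifted list and called 0 of the unchanged lists. Genes were simulated independently of each other and without array sets. The simulation therefore cannot show how often correlated genes or array sets give false calls of lists or genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.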

Results

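RNA levels were measured in cultures of 31 normal human cell types on 61 arrays, with 1 to 6 arrays per type. The cultures comprised 16 endothelial, 26 smooth muscle, 7 fibroblast, 6 stromal and 6 epithelial arrays, where stromal is the word the titles use. Of the types, 14 had a single array and 17 had more. The arrays fell into 3 sets of 28, 27 and 6, found from probes in 1 of 2 states that cut across lineages. No type lay in more than 1 set (0 of 31), and no label shows whether the sets are technical. Array medians were 1 to 1.002 in set 2 and 1.011 to 1.02 elsewhere, so scaling followed the sets. Set 2 held the iliac and umbilical artery endothelial, pulmonary artery, tibial artery and bladder smooth muscle, hepatic and pooled dermal fibroblast, and cardiac and mammary stromal cultures. Set 3 held the bladder microvascular and saphenous vein endothelial cultures and the hepatic artery, hepatic vein and popliteal artery smooth muscle cultures. Comparisons are given with and without the array set where possible, and within sets that hold both sides. The set cannot be estimated for arterial against microvascular endothelial cultures. For iliac against umbilical artery and renal against genital cultures both sides lie in 1 set, so adding the set changes no value. Agreement in direction within sets reuses the arrays that gave the calls, so it tests little.

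Arrays of one cell type resembled each other more than arrays of different types of one lineage. Those in turn were more alike on average than arrays of different lineages. The mean correlation across genes was 0.969 ± 0.0159 (SD, 53 pairs) within a type, 0.927 ± 0.0248 (443 pairs) between types of one lineage and 0.856 ± 0.0494 (1334 pairs) between lineages. The difference of 0.0419 between the first and second means had a permutation p of 1e-05, the smallest that the permutations can give. Within array sets the difference was 0.0361. The best correlated other array was of the same lineage for 58 of 61 arrays, against at most 36 when lineage labels were shuffled over single arrays. It was of the same type for 40 of the 47 arrays whose type had several. The shuffle ignored that arrays of one type share a lineage, so it overstates the evidence for lineages. The 3 arrays with a best match outside their lineage are stromal: the mammary and prostate stromal arrays were nearest to smooth muscle and the skeletal muscle stromal array to a fibroblast array. The cardiac stromal, all fibroblast and both renal epithelial arrays matched their own type. So no stromal or fibroblast array (0) was nearest to another type of its own lineage. No pair of arrays was identical, and the highest r was 0.99.

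**Figure D1:**
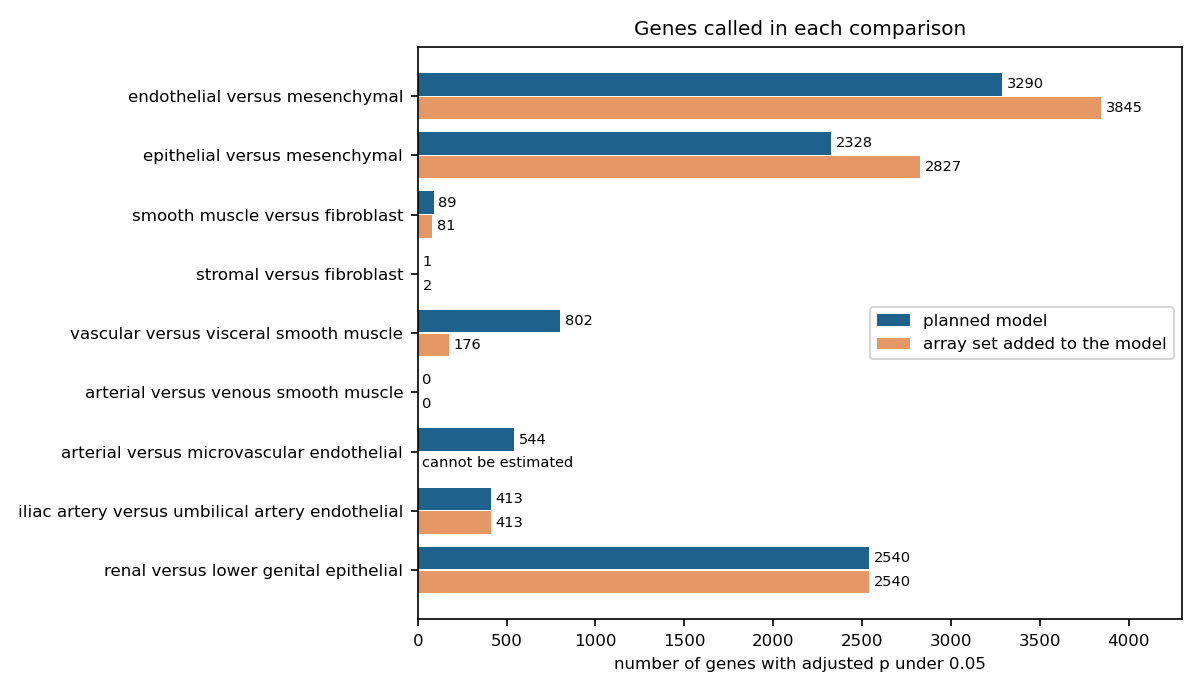
Number of genes with an adjusted p under 0.05 in each comparison (horizontal axis), in the planned model and with the array set added. Endothelial, renal and epithelial contrasts call 3290, 2540 and 2328 genes, while stromal against fibroblast calls 1 and arterial against venous smooth muscle 0.

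Endothelial cells line blood vessels, and the first comparison asked what sets their cultures apart from the mesenchymal ones. The list of endothelial genes was higher, and the fibroblast, collagen and matrix, and regional regulator lists were lower. Of 9655 genes, 3290 were called, 1765 higher and 1525 lower, and 1137 of them differed by at least 1 log2 unit. CDH5, the cadherin of endothelial junctions, was higher by 6.18 ± 0.39 log2 units (SE, adjusted p 2.73e-20), at 3.79 ± 0.39 in endothelial and -2.23 ± 0.99 in mesenchymal arrays. ECSCR, a surface regulator of endothelial migration, was higher by 6.88 ± 0.58 (adjusted p 2.43e-15), and ANGPT2, a ligand of the TIE2 receptor, by 5.72 ± 0.65 (adjusted p 1.25e-10). The GTPases GIMAP4 and GIMAP6 were higher by 7.16 ± 0.44 and 7.01 ± 0.52 (GIMAP6 lay at -1.73 ± 1.18, adjusted p 0.274, with exact zeros read as 0, where another probe stood for it), and the granule protein multimerin (MMRN1) by 6.71 ± 0.52. The adhesion protein MPZL2, the NAD-synthesis enzyme NMNAT1, the actin-associated FAM107A and the secreted CYTL1 were higher by 6.59, 6.53, 6.31 and 5.92. GIMAP4, MPZL2 and CYTL1 lie near the array floor in mesenchymal cultures, which limits the size of their differences.

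The largest fall was in decorin (DCN), a small proteoglycan that binds collagen, at -6.76 ± 0.49 (adjusted p 8.84e-18), from 6.15 ± 0.69 in mesenchymal to -0.76 ± 1.41 in endothelial arrays. Lumican (LUM), a proteoglycan of the same family, was lower at -6.00 ± 0.51. The fibrillar collagen genes COL1A2, COL3A1 and COL1A1 were lower at -6.28, -6.27 and -6.01, the microfibrillar COL6A3 at -5.65, and PCOLCE, which aids procollagen cleavage, at -5.37. HAS2 makes hyaluronan and TNFAIP6 binds it, and they were lower at -5.59 and -5.42. The transcription factors SNAI2 and TWIST1, which drive mesenchymal programmes, were lower at -5.35 ± 0.31 (adjusted p 6.14e-22) and -5.14 ± 0.42, and the fibroblast calcium-binding protein S100A4 at -4.91 ± 0.65. Actin-binding genes of smooth muscle were lower too: TAGLN at -3.34 ± 0.58, CNN1 at -3.20 ± 0.50, SYNPO2 at -2.50 ± 0.65 and TPM2 at -2.11 ± 0.25. The arterial regulator SOX17 was higher by 4.26 ± 0.87, the TGF-beta family receptor ACVRL1 by 2.76 ± 0.28, the chemokine receptor CXCR4 by 2.33 ± 0.38 and NOTCH1 by 1.72 ± 0.27. Of the venous and lymphatic genes, the hyaluronan receptor LYVE1 was higher by 2.09 ± 0.38, the venous ephrin receptor EPHB4 by 1.58 ± 0.24 and the scavenger receptor STAB1 by 1.29 ± 0.11, while the lymphatic mucin PDPN, near the floor in endothelial cultures, was lower at -2.50 ± 0.61. Of the 34 called genes named here, 33 lay on the stated side of the mesenchymal mean on every endothelial array, and LYVE1 on 15 of 16.

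The endothelial list had 19 of 20 genes higher, 0 lower and 1 not past the threshold, 19 adjusted over the list alone, with a median difference of 3.65 (camera adjusted p 9.59e-29, and 0.000317 with an estimated correlation). The fibroblast list had 14 of 15 lower and 0 higher, 15 adjusted over the list alone, with a median of -2.92 (1.52e-13, estimated 0.000372). Of 29 collagen and matrix genes 19 were lower and 1 higher, the same adjusted over the list alone, with a median of -1.63 (4.66e-10, estimated 0.0327). Of 18 regional mesenchyme regulators 11 were lower and 0 higher, 14 adjusted over the list alone, with a median of -1.06 (5.66e-05, estimated 0.0247). The next lists were called only with the preset correlation. Sterol and lipid synthesis had 10 of 13 higher, 11 adjusted over the list alone (4.22e-05, estimated p 0.239), and proliferation 8 of 25 higher, 8 adjusted over the list alone (0.0464, estimated p 0.823). The arterial list had 6 of 13 higher and 2 lower, 8 and 2 adjusted over the list alone (0.0364, estimated p 0.239). Renal tubule genes had 3 of 6 lower, 4 adjusted over the list alone (0.0465, estimated p 0.144), and vasoactive and hormone receptors 9 of 18 lower and 2 higher, 11 and 2 adjusted over the list alone (0.0465, estimated p 0.0999). With the array set in the model the list medians of the endothelial, fibroblast and collagen lists were 3.61, -3.22 and -2.09, and the renal tubule and receptor calls were lost (0.0546 each).

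The other 15 lists were not called, although single members were. Higher and lower counts were 3 and 1 of 10 venous and lymphatic genes, 3 and 0 of 8 microvascular genes, 0 and 5 of 15 smooth muscle contractile genes (camera adjusted p 0.0516), 4 and 4 of 23 simple epithelial genes, 1 and 0 of 20 stratified epithelial genes and 1 and 0 of 5 skeletal myoblast genes. Of 9 HOX paralogs 1 to 5, 3 were higher and 2 lower; of 3 paralogs 6 to 8, 2 were higher and 1 lower; and of 2 paralogs 9 to 13 neither was called. TGF-beta and Notch targets had 1 of 17 higher and 6 lower, interferon response genes 4 and 5 of 16, and inflammatory genes 1 and 5 of 19. Stress genes had 0 of 14 higher and 4 lower, leukocyte and blood genes 0 and 2 of 5, and melanocyte and neural genes 0 and 0 of 4. Median, mean and test differed in sign for the simple epithelial list (-0.12, 0.02, down), the interferon list (0.14, 0.12, down) and the inflammatory list (0.01, -0.39, down). Of the 3290 genes, 3164 were also called with the array set in the model (3845 in all). Within sets 1, 2 and 3 alone, 948, 1535 and 1779 genes were called, and 99.6%, 99.9% and 98.6% of the 3290 had the same direction.

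**Figure D2:**
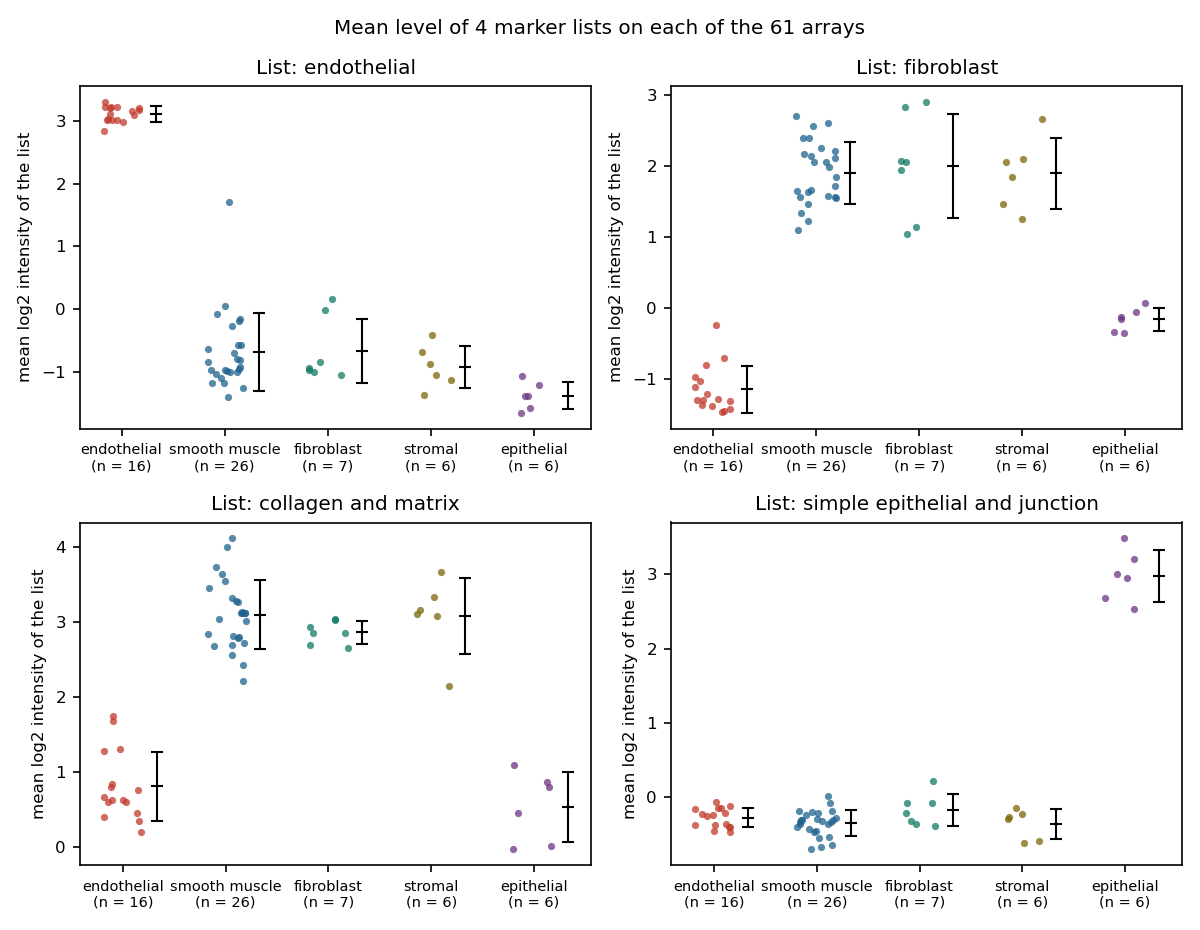
Mean log2 intensity of 4 marker lists (vertical axes) on each array, grouped by lineage, with the mean and SD of each lineage beside the points. Endothelial, mesenchymal and epithelial cultures separate, 1 smooth muscle array at 1.71 stands above its lineage on the endothelial list, and smooth muscle, fibroblast and stromal cultures overlap on all 4 lists.

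Epithelial cultures were compared with the mesenchymal ones in the same way. The simple and stratified epithelial lists were higher, the stratified one through the genital cultures, and the collagen and matrix list was lower. Of 9655 genes, 2328 were called, 1055 higher and 1273 lower, and 1184 differed by at least 1 log2 unit. S100A14, an epithelial calcium-binding protein, was higher by 7.53 ± 0.31 (adjusted p 1.23e-28), the keratinocyte cell cycle regulator stratifin (SFN) by 7.28 ± 0.33, and the vesicle transport gene RAB25 by 6.63 ± 0.20 (adjusted p 5.36e-36). The adhesion genes EPCAM and CDH1 were higher by 6.35 ± 0.32 and 6.19 ± 0.27, and the surface sialoglycoprotein CD24 by 6.79 ± 0.72. The protease inhibitor SPINT2, the growth factor carrier FGFBP1, the epidermal protease KLK7, the zinc finger gene ZBED2 and the antimicrobial S100A9 were higher by 6.89, 6.75, 6.44, 6.29 and 6.22. KLK7 and EPCAM lie near the floor in mesenchymal cultures. The basal keratin KRT5 and the cornified envelope gene SPRR1B were higher by 6.12 ± 0.72 and 5.78 ± 0.64, but KRT5 had an SD of 4.83 among the 6 epithelial arrays because the renal cultures lacked it.

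Decorin was again the largest fall, at -6.23 ± 0.64, followed by the collagen cross-linking enzyme LOX at -6.14 ± 0.58 and COL1A2 at -5.83 ± 0.89. TNFAIP6, COL6A3, COL3A1, COL6A1 and PCOLCE were lower at -5.29, -5.28, -5.26, -5.05 and -5.00. The forkhead gene FOXF1, a regulator of gut and lung mesenchyme that lies near the floor in epithelial cultures, was lower at -5.09 ± 1.10 (adjusted p 0.000284), and the matrix protease MMP3 at -4.91 ± 1.14 (adjusted p 0.000695). TWIST1 and LUM were lower at -4.74 ± 0.54 and -4.04 ± 0.66, TAGLN at -3.83 ± 0.75, SYNPO2 (near the floor) at -2.84 ± 0.84, CNN1 at -2.68 ± 0.65 and TPM2 at -2.25 ± 0.32. The elastic fibre gene FBLN2 was lower at -2.87 ± 0.88 (adjusted p 0.012), but not with the array set in the model (-2.07 ± 0.84, adjusted p 0.0545). Of the HOX genes, HOXD1 (near the floor in mesenchymal cultures) was higher by 1.58 ± 0.46 and HOXA2 by 1.23 ± 0.47 (adjusted p 0.0489), while HOXD1 fell to 0.28 (adjusted p 0.71) without the renal cultures, and HOXD4 and HOXB4 did not pass (adjusted p 0.0844 and 0.455). Of the 32 called genes, HOXD1, HOXA2, FBLN2 and SYNPO2 lost their call without some array or type. All but 1 of the 32 lay on the stated side of the mesenchymal mean on every epithelial array, and HOXD1 on 5 of 6.

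The simple epithelial and junction list had 22 of 23 genes higher, 22 adjusted over the list alone, with a median of 3.13 (camera adjusted p 1.84e-37, estimated 7.95e-12). All 20 stratified epithelial genes were higher, also adjusted over the list alone, with a median of 4.37 (1.33e-30, estimated 0.0131), but renal cultures had all 20 lower than the genital ones, with a median of -6.24, so the list marks the cervical and vaginal cultures. Collagen and matrix had 17 of 29 lower and 0 higher, 21 adjusted over the list alone, with a median of -2.36 (2.43e-10, estimated 0.0316). The estimated correlation removed the other 5 calls. These were the fibroblast list with 9 of 15 lower, 9 adjusted over the list alone (9.38e-06, estimated p 0.061), sterol and lipid synthesis with 9 of 13 higher, 11 adjusted over the list alone (2.08e-07, estimated p 0.0999), and proliferation with 6 of 25 lower, 6 adjusted over the list alone (0.0233, estimated p 0.803). Smooth muscle contractile genes had 5 of 15 lower, 5 adjusted over the list alone (0.0333, estimated p 0.375), and TGF-beta and Notch targets 8 of 17 lower and 2 higher, the same adjusted over the list alone (0.0465, estimated p 0.378). Those last lists were not called with the array set in the model (0.123 and 0.229), while the epithelial, stratified and collagen medians were then 3.07, 4.44 and -2.05. Endothelial genes had 0 of 20 higher and 2 lower, and HOX paralogs 1 to 5 had 3 of 9 higher and 0 lower, without a call of the list. With the array set in the model 2827 genes were called, 2102 of them shared. All epithelial arrays belong to set 1, where 1781 genes were called and all 2328 kept their direction. Without the cervical cultures 1457 genes were called, and without them or the vaginal cultures the epithelial side rests on 2 types.

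Few genes were called between smooth muscle and fibroblast cultures, and no listed contractile gene was, with ACTA2 and MYH11 unmeasured. In limma 89 genes were called, 38 higher and 51 lower in smooth muscle (1630 at an unadjusted p under 0.05), and 26 differed by at least 1 log2 unit. PDLIM4, a LIM protein of actin fibres, was higher by 1.48 ± 0.29 (adjusted p 0.00596), and the proline synthesis enzyme PYCR1 by 1.34 ± 0.28 (adjusted p 0.0164). P4HA1, which hydroxylates collagen prolines, was higher by 1.35 ± 0.30 (adjusted p 0.023), the actin cross-linker MARCKS by 1.32 ± 0.33, the phosphoinositide phosphatase INPP5F by 1.06 ± 0.25 and the tubulin TUBB3, a member of the neural list, by 1.41 ± 0.37. CNN2, COPB2, MAGEH1 and ITGB5, genes of actin, vesicle coats, an adaptor and an integrin, were higher by 1.15, 1.09, 1.07 and 1.01. With the array set in the model they stayed higher but were not called (adjusted p 0.0606, 0.0692, 0.101 and 0.0534). Lower were the deacetylase HDAC6 at -1.77 ± 0.31 (adjusted p 0.00131), the imprinted gene PEG3 at -1.94 ± 0.47, the dermal matrix gene DPT at -1.72 ± 0.41, the antimicrobial peptide gene LEAP2 at -1.23 ± 0.26 and the membrane gene TMCC3 at -1.18 ± 0.29. SRD5A2, which makes dihydrotestosterone, was lower at -2.01 ± 0.47, SLC9A9, an endosomal ion exchanger, at -1.48, the elastase MMP12, near the floor, at -1.31, lanosterol synthase LSS at -1.30 and mitochondrial FASTKD1 at -1.23. With the array set in the model these 5 were not called (adjusted p 0.0549, 0.0506, 0.0786, 0.0606 and 0.0722).

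SRD5A2 and TMCC3 were brightest in the pooled dermal fibroblasts (3.57 and 2.79). Among contractile genes, TPM1 (1.13 ± 0.41, adjusted p 0.136), PLN, LMOD1 and ACTG2 (0.72 ± 0.51, adjusted p 0.474) did not pass, and PLN changed sign with the array set in the model (-0.86 and 0.35). The fibroblast genes TWIST2, CXCL12 and MFAP5, the matrix genes MMP3, FBN1, MMP1 and COL6A1, and the sterol genes IDI1, FDPS and DHCR7 did not pass either. Of 15 contractile genes 0 were higher, 0 lower and 15 not past the threshold (median -0.08, 0 adjusted over the list alone). Of 15 fibroblast genes only DPT was lower (list median 0.04, mean -0.05, test down), of 29 matrix genes none passed (0), of 13 sterol genes 1 was lower and of 4 melanocyte and neural genes 1, TUBB3, was higher. The count of 24 lists called by camera was 0, and also 0 with an estimated correlation and 0 with the array set. With the array set 81 genes were called, 54 of them shared with the 89. Within set 1 (14 and 3 arrays) 1 gene was called and within set 2 (9 and 4 arrays) 0, and all 89 had the same direction in both. Of the 20 genes named, 14 lay on the stated side of the fibroblast mean on all 26 smooth muscle arrays and the others on at least 24.

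The 89 calls hung on few cultures. Without the pooled dermal fibroblasts, the only type titled neonatal and pooled, 3 genes were called. Age and pooling cannot be told apart from that type. SRD5A2, DPT, MMP12 and TMCC3 then fell to -0.16, -0.41, -0.13 and -0.06, so their differences rest largely on that type, while PDLIM4 kept 1.07 without its call (adjusted p 0.444). There were 51 calls without the lung fibroblasts (HDAC6, 0.0601). Leaving out hepatic fibroblast array 1 gave 184 calls, hepatic fibroblast array 2 gave 29, pooled dermal fibroblast arrays 1 and 2 gave 15 and 25, and the popliteal artery or popliteal vein culture 52 each. Without the colon, pulmonary artery and urethra types the counts were 153, 142 and 58. Of the 20 called genes named, 16 lost their call without some single array and 20 without some type.

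Cultures titled stromal could not be told from fibroblast cultures as a class, with a single exception. GALNT6, an enzyme that starts mucin-type sugar chains, was lower in stromal cultures at -3.67 ± 0.69 (adjusted p 0.0166), at -1.53 ± 0.98 in 6 stromal and 2.46 ± 0.95 in 7 fibroblast arrays, and lower on 6 of 6 stromal arrays than the fibroblast mean. It was the only called gene (812 had an unadjusted p under 0.05), and with the array set in the model its difference was -3.78 ± 0.61 (adjusted p 0.000694) beside 1 other call. The fibroblast genes DPT (-1.59 ± 0.51, adjusted p 0.454), S100A4, TWIST2 and DCN, the matrix genes MMP3, FBN1, LOXL1 and COL8A1, and the contractile genes CNN1 (-2.47 ± 0.79, adjusted p 0.454), SMTN, SYNPO2 and LMOD1 did not pass. By camera 0 of 24 lists were called, also 0 with an estimated correlation. Of 15 contractile genes 0 passed and 2 were lower adjusted over the list alone, of 15 fibroblast genes 0 and 1, and of 29 matrix genes 0 and 0. Within set 1 (2 and 3 arrays) 0 genes were called, and within set 2 (4 and 4 arrays) 1, another gene in the other direction. Without the cardiac stromal, lung fibroblast, pooled dermal fibroblast or prostate stromal cultures 0 genes were called, without the mammary culture 7, without the hepatic fibroblasts 3, and without skeletal muscle stromal or pooled dermal fibroblast array 2 there were 2. GALNT6 had an adjusted p of 0.417 without the cardiac stromal cultures.

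Smooth muscle of blood vessel walls was set against smooth muscle of hollow organs, prostate and spleen. The proliferation list was lower in vessel cultures with the preset correlation only, and the regional regulator list was not called. Of 9655 genes, 802 were called, 408 higher and 394 lower in vascular cultures, and 234 differed by at least 1 log2 unit. LMO2, a LIM regulator of vessels and blood, was higher by 4.41 ± 0.64 (adjusted p 0.000215), the ankyrin ANK3 by 4.05 ± 0.40 (adjusted p 1.56e-06), and the transcription factor SOX17 by 3.68 ± 0.65 (adjusted p 0.00163). HSPB2 and CRYAB, neighbouring small heat shock genes of muscle, were higher by 4.03 ± 0.58 and 3.86 ± 0.68, the adipose-associated MEDAG by 3.98 ± 0.64, the matrix gene MEGF6 by 3.34 ± 0.40 and the steroid dehydrogenase AKR1C3 by 3.28 ± 0.52. PTGIS, which makes the vasodilator prostacyclin, was higher by 4.96 ± 1.12 (adjusted p 0.00884), and FBLN2 by 3.40 ± 0.81, but not with the array set in the model (PTGIS 3.66 ± 1.12, adjusted p 0.0859, and FBLN2 0.115). The prostaglandin receptor PTGFR was higher by 1.83 ± 0.34 (adjusted p 0.00208, and 0.0353 with the set) and the TGF-beta co-receptor ENG by 1.35 ± 0.25 (0.00212 and 0.0142). The receptors ESR1 and TEK and the actin-associated SVIL were higher by 1.50, 1.35 and 0.84. With the set, at 1.24, 1.52 and 0.755, they lost their call (adjusted p 0.173, 0.0642 and 0.124).

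The irritant-gated channel TRPA1 showed the largest fall, at -5.50 ± 0.78 (adjusted p 0.000185), from 3.53 ± 2.39 in visceral to -2.06 ± 0.55 in vascular arrays. FOXF1 was lower at -3.68 ± 0.88 (adjusted p 0.0124, and 0.0338 with the array set), the matrix protein gene SPON2 at -3.70 ± 0.71, the signalling adaptor CARD9 at -2.88 ± 0.42, tissue factor (F3) at -2.72 ± 0.55 and the lectin CLEC2B at -2.46 ± 0.47. OTULINL, the hormone gene CGA, TFAP2C and the HOX gene HOXD11 were lower at -3.03, -2.75, -2.66 and -2.45. With the set, at -2.60, -2.28, -2.42 and -2.29, they were not called (adjusted p 0.11, 0.0839, 0.0884 and 0.168). CGA, TFAP2C and HOXD11 lie near the floor in vascular cultures. HOXC6 was higher by 0.68 ± 0.13 (0.00225, and 0.00288 with the set) and HOXC5 by 0.62 ± 0.17 (0.0251, and 0.0973 with the set), while HOXB7 and HOXC10 did not pass. GATA6, ISL1 and the hindlimb regulator PITX1 (-1.49 ± 0.60, adjusted p 0.117) did not pass, but PITX1 did with the set (-2.39 ± 0.63, adjusted p 0.0482). The contractile genes SYNPO2, ACTG2 and TAGLN, the bradykinin receptors BDKRB1 and BDKRB2, and the endothelial genes ESM1 and ECSCR did not pass. Of the 27 called genes named, 19 lay on the stated side of the visceral mean on all 12 vascular arrays and the others on at least 9.

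Proliferation genes were lower in 12 of 25, 20 adjusted over the list alone, with a median of -0.81 (camera adjusted p 1.6e-10, estimated p 0.375; median -0.64 and 5.46e-09 with the array set). Interferon genes were higher in 3 of 16, 4 adjusted over the list alone, with a median of 0.64 (0.000546, estimated p 0.357; 0.52 and 0.000205 with the set). Collagen and matrix had 3 of 29 higher, 7 adjusted over the list alone (0.00309, estimated p 0.49), and the fibroblast list 5 of 15 higher, 6 higher and 1 lower adjusted over the list alone (0.00719, estimated p 0.239). Endothelial genes, ENG and TEK, were higher in 2 of 20, also adjusted over the list alone (0.0333, estimated p 0.756). Without pulmonary artery smooth muscle array 3, which stands apart on this list, the same 2 were higher (list 0.0337, estimated p 0.63). The matrix, fibroblast and endothelial lists stayed called with the set (0.0406, 0.0344 and 0.0344). TGF-beta and Notch targets had 1 of 17 higher, 3 adjusted over the list alone (0.0292, estimated p 0.375), and lost their call with the set (0.088). Not called were contractile genes (1 of 15 higher), regional regulators (2 of 18 higher and 1 lower), receptors (3 of 18 higher, with median -0.10 and mean 0.05 of opposite sign) and the HOX lists (1 of 9 higher, 1 of 3 higher, 1 of 2 lower).

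The array set weighed on this comparison. With it in the model 176 genes were called, 167 of them among the 802. Within set 1 (3 and 11 arrays) 22 genes were called and 801 of the 802 had the same direction, and within set 2 (6 and 3 arrays) 0 were called and 765 (95.4%) had the same direction. Without the hepatic vein, renal vein or ureter culture 342, 389 or 512 genes were called, and without the prostate or urethra types 428 or 452. Of 27 called genes, ESR1, FBLN2, HOXC5, HOXD11, SVIL and TEK lost their call without some single array, and OTULINL without some type.

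Arterial and venous smooth muscle (9 arrays of 5 types against 3 of 3) gave no gene past the threshold. In limma 0 of 9655 genes were called, 569 had an unadjusted p under 0.05, and the smallest adjusted p was 0.547. With the array set in the model 0 were called and 873 had an unadjusted p under 0.05. SOX17 lay at 4.66 ± 1.93 in arterial and 1.26 ± 1.11 in venous cultures, a difference of 2.77 ± 0.96 that did not pass (adjusted p 0.754). The contractile genes SYNPO2 (-1.73 ± 1.18, adjusted p 0.903), MYLK, CNN1 and TAGLN, the arterial genes UNC5B, NOTCH4 and GJA4, and the venous and lymphatic genes RELN (adjusted p 0.861), EPHB4, LYVE1 and PDPN did not pass. The arterial (13 genes), venous (10) and contractile (15) lists each had 0 genes past the threshold, also 0 adjusted over the list alone. Camera called the interferon list, lower in arterial cultures with a median of -0.89 (adjusted p 5.66e-05, estimated p 0.239; -0.90 and 2.18e-06 with the set), though 0 of its 16 genes passed and 1 was lower adjusted over the list alone. It also called proliferation, with a median of 0.17 and 0 of 25 genes past the threshold, also 0 adjusted over the list alone (0.0465, estimated p 0.817; 0.49 and 4.3e-05 with the set). Within set 1 (1 and 2 arrays) 9 genes were called and within set 3 (2 and 1 arrays) 0, where a lone array is assumed to vary like the other groups.

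Arterial endothelial cultures (10 arrays of 2 types) were compared with microvascular ones (4 of 3 types). All arterial arrays lie in set 2 and no microvascular array does (0), so array set and vessel class cannot be told apart and every difference in this comparison is open to a set effect. Of 9655 genes, 544 were called, 275 higher and 269 lower in arterial cultures. The retinoid-synthesis gene ALDH1A1 was higher by 4.71 ± 0.57 (adjusted p 8.12e-05), at 3.86 ± 0.96 against -0.77 ± 0.61. Phospholamban (PLN), haemoglobin HBB, synapsin SYN1, the growth factor IGF1, the calcium receptor CASR, antithrombin SERPINC1, ZFR2, the peptidase TRHDE and the phosphatase PTPRO were higher by 3.55, 3.38, 2.99, 2.88, 2.79, 2.79, 2.78, 2.77 and 2.72, each from near the floor. HBB, SYN1, IGF1, CASR, SERPINC1 and PTPRO belong to probes in 2 states between sets. Here that means that arrays of sets 1 and 2 do not overlap within any mesenchymal lineage. Between set 2 and the other sets HBB differed by 3.62 among mesenchymal types too. Lower were the adhesion receptor ADGRF5 at -4.17 ± 0.65 (adjusted p 0.000997), the phosphatase PTPRN2 at -3.33 ± 0.73, phosphodiesterase PDE2A at -2.99 ± 0.75 (but -1.61 ± 1.00, adjusted p 0.381, with exact zeros read as 0), NEURL1B (near the floor) at -2.77 ± 0.54 and the microvascular transcription factor TCF15 at -2.34 ± 0.59. SYBU, GMFG, MRPS18C, ZNF385D and the channel TRPV2 were lower at -2.33, -2.31, -2.31, -2.13 and -2.04. In the same direction, PLN, ZFR2, TRHDE, NEURL1B, SYBU, ZNF385D and TRPV2 differed between the sets among mesenchymal types by 2.28, 0.81, 0.72, -1.01, -0.26, -0.52 and -0.68. Among mesenchymal types ALDH1A1, ADGRF5, PTPRN2, PDE2A, TCF15, GMFG and MRPS18C differed between the sets by -0.46, 0.06, 0.17, 0.17, 0.65, 0.60 and 0.11, against the sign of the endothelial difference.

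The vascular growth factor receptor KDR was lower in arterial cultures at -1.68 ± 0.30 (adjusted p 0.00316) and PECAM1 at -0.93 ± 0.16 (0.00196), while MMRN1 was higher by 1.08 ± 0.21. The gap junction gene GJA4, on the arterial list, was lower in arterial cultures at -1.01 ± 0.20 (adjusted p 0.00741). HEY2 (1.40 ± 0.65, adjusted p 0.226), GJA5, DLL4, LYVE1, NRP2, RELN, PROX1, RGCC, LPL, FABP4, EMCN, CD79A, CD68 and LYZ did not pass. Of smooth muscle genes, LMOD1 was higher by 2.17 ± 0.38, SYNPO2 (near the floor) by 1.36 ± 0.35 and MYLK lower at -1.54 ± 0.30. Among mesenchymal types PECAM1, MMRN1, GJA4, LMOD1, SYNPO2 and MYLK differed between the sets in the same direction, by -0.13, 0.41, -0.64, 1.06, 0.75 and -0.92, and KDR in the other, by 0.39. The contractile list had 3 of 15 higher and 1 lower, the same adjusted over the list alone (camera adjusted p 0.0214, estimated p 0.239), and HOX paralogs 1 to 5 had 1 of 9 higher, 4 adjusted over the list alone (0.00333, estimated p 0.239). The endothelial list had 1 of 20 higher and 2 lower, 3 and 2 adjusted over the list alone, the arterial list 0 of 13 higher and 1 lower (median -0.09, mean 0.15, test up), the venous list 0 of 10 (0.05, -0.26, down), the microvascular list 1 of 8 lower and the leukocyte list 1 of 5 higher (HBB, with median -0.25 against an upward test), none of them called. Of the 27 called genes, 26 lay on the stated side of the microvascular mean on all 10 arterial arrays, and SYNPO2 on 9. Without the umbilical, iliac or uterine cultures 110, 212 or 204 genes were called, and without uterine array 1 there were 326. MRPS18C, PDE2A, SYNPO2 and TCF15 lost their call without some single array, and 13 of the 27 without some array or type, GJA4, LMOD1, MMRN1, MYLK, NEURL1B and PTPRN2 among them.

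**Figure D3:**
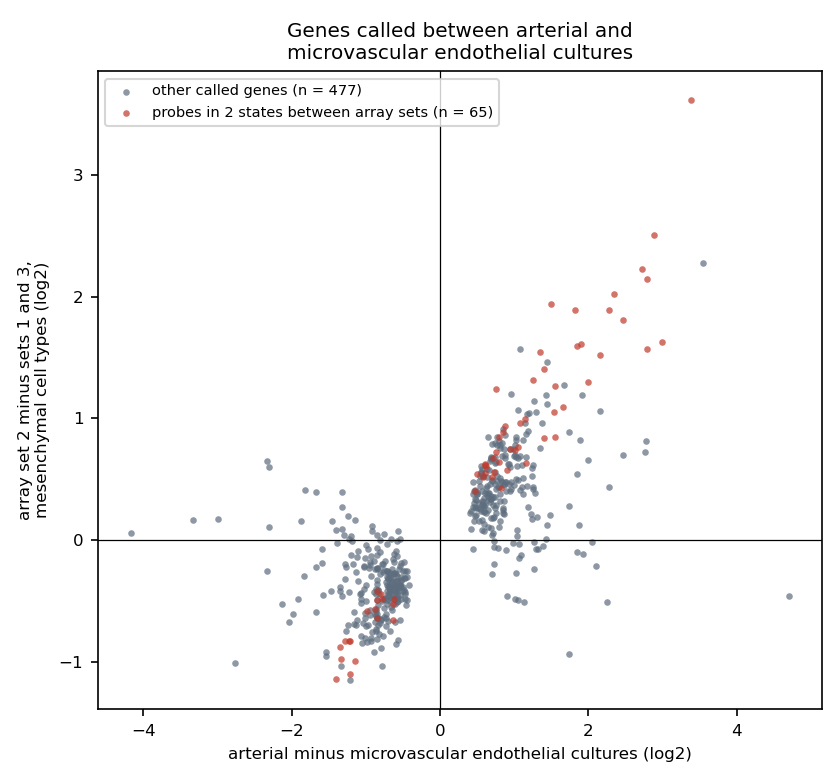
Difference between arterial and microvascular endothelial cultures (horizontal axis, log2) against the difference between set 2 and the other array sets among mesenchymal cell types (vertical axis, log2), for the called genes. Of the 477 genes not on probes in 2 states 88.7% have the same sign on both axes. The 65 on such probes all do, but were picked to differ by set.

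Iliac and umbilical artery endothelial cultures, 4 and 6 arrays of the same set, differed in single genes of several kinds. The interferon list and HOX paralogs 1 to 5 were called with the preset correlation only (estimated p 0.125 each), and the matrix list was not called. In limma 413 genes were called, 177 higher and 236 lower in iliac cultures, and 131 differed by at least 1 log2 unit. The interferon-inducible GTPase MX1 was higher by 3.85 ± 0.65 (adjusted p 0.000397), but by 0.14 ± 0.37 (adjusted p 0.911) with exact zeros read as 0, where another probe stood for it. Also higher were the proteasome subunit PSMB9 by 3.40 ± 0.36 (1.69e-07), the membrane protein IFITM1 by 3.16 ± 0.51 (0.000168), IFIT1 by 2.43 ± 0.48 and IFI44L by 2.31 ± 0.46. The matrix gene periostin (POSTN) was higher by 5.00 ± 1.00 (adjusted p 0.00272), at 3.50 ± 2.47 against -1.50 ± 0.81, and the sulfatase SULF1 by 3.48 ± 0.73. The Wnt inhibitor DKK2 (near the floor in umbilical cultures), the steroid dehydrogenases AKR1C3 and AKR1C1 and the apolipoprotein APOL3 were higher by 3.23, 2.90, 2.53 and 2.66. HOXD1 and HOXD4, both of the HOXD cluster, were higher by 1.95 ± 0.27 (adjusted p 3.43e-05) and 1.44 ± 0.26 (adjusted p 0.00102), while HOXB3, HOXD8, HOXB7 and HOXC6 did not pass. HOXA2 stays open, since 3 of the 4 iliac arrays hold an exact zero for it. Its test rests on 1 iliac array and did not pass, and with the zeros read as 0 it was lower at -4.16 ± 0.68 (adjusted p 0.000263), against the direction of the HOX list. COL8A1 was higher by 2.07 ± 0.55 (adjusted p 0.0263), CLDN5, a claudin of endothelial junctions, by 1.16 ± 0.28 and KDR lower at -1.13 ± 0.24.

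The G-protein regulator RGS5 showed the largest fall in iliac cultures, at -4.81 ± 0.34 (adjusted p 1.18e-11), from 5.32 ± 0.77 in umbilical to 0.51 ± 0.58. The protease inhibitor TFPI2 was lower at -4.61 ± 0.44 (adjusted p 1.71e-08), the synaptic adhesion gene NRXN3 at -3.33 ± 0.57, the homeobox gene ALX1 (near the floor) at -2.77 ± 0.44 and the transcription factor GATA3 at -2.74 ± 0.53. The collagenase MMP1, which lies near the upper limit of the arrays, was lower at -3.65 ± 1.02 (adjusted p 0.0342), CLDN11 at -2.65 ± 0.73, the endothelial sialomucin EMCN at -2.35 ± 0.49, the adhesion receptor ADGRL2 at -2.28 ± 0.49 and CRACD at -2.26 ± 0.42. COL1A2 (1.50 ± 0.79, adjusted p 0.284), MMRN2, S100A4, FAP, DCN and FBLN2 did not pass. Of 26 called genes, 25 lay on the stated side of the umbilical mean on all 4 iliac arrays, and MMP1 on 3.

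Interferon genes were higher in 9 of 16 and lower in 0, 12 adjusted over the list alone, with a median of 1.30 (camera adjusted p 8.71e-11, estimated p 0.125). Of HOX paralogs 1 to 5, 3 of 9 were higher, 5 adjusted over the list alone (0.00466, estimated p 0.125), and of sterol genes 3 of 13, 5 adjusted over the list alone (0.000687, estimated p 0.382). Without iliac array 1 and pulmonary artery smooth muscle array 3 none of the 13 sterol genes was higher (0; list 0.00109, estimated p 0.426), with 7 of 16 interferon genes (1.17e-12, estimated p 0.0926) and 2 of 8 HOX paralogs 1 to 5 (0.0147, estimated p 0.22). The endothelial list (1 of 20 higher, 2 lower, median 0.06 and mean -0.07 of opposite sign), collagen and matrix (2 and 2 of 29, median -0.07 and mean 0.12 of opposite sign), the fibroblast list (0 of 15) and HOX paralogs 6 to 8 (0 of 3) were not called. Fitted to set 2 alone, 304 genes were called. Both types lie in that set, so the shared direction of all 413 is by construction and tests nothing. The count depended on single arrays: 130, 206 and 132 without iliac arrays 1, 4 and 5, and 160, 199, 186 and 787 without umbilical arrays 2, 4, 5 and 6. Without iliac array 1, which carried more mesenchymal transcripts than the other iliac arrays, POSTN remained called (4.35 ± 1.08, adjusted p 0.0291), COL8A1 did not (1.99 ± 0.61, adjusted p 0.0977), and CLDN11, CLDN5 and MMP1 lost their call without some other or the same single array.

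Renal epithelial cultures (2 arrays) and cultures of the lower genital tract (cervical and vaginal, 4 arrays) represent simple and stratified epithelium. The stratified epithelial list was lower in renal cultures, while the renal tubule list was not called. Of 9647 genes, 2540 were called, 1257 higher and 1283 lower in renal cultures, and 1235 differed by at least 1 log2 unit. Osteopontin (SPP1), secreted by tubule cells, was higher by 7.82 ± 0.48 (adjusted p 3.12e-15), at 5.80 ± 0.06 against -2.02 ± 0.38. The methyltransferase NNMT, the ciliary gene DCDC2, the brush border peptidase DPP4, the sodium pump subunit FXYD2 and the potassium channel KCNJ16 were higher by 6.63, 6.37, 6.19, 5.99 and 5.85. The protease MMP7, the lectin SIGLEC15, the apical sorting gene MAL and the tubule basement membrane gene TINAG were higher by 5.38, 5.25, 4.98 and 4.94. KCNJ16 and TINAG lie near the floor in genital cultures. The kidney regulator EMX2, near the floor in genital cultures, was higher by 4.35 ± 0.47 (adjusted p 6.64e-09) and the kidney cadherin CDH6 by 2.83 ± 0.88 (adjusted p 0.0154), CA12 was lower at -1.30 ± 0.42 and the peptidase MME did not pass (adjusted p 0.0632).

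The basal keratins KRT5 and KRT14 were lower at -9.35 ± 0.27 (adjusted p 3.66e-24) and -9.24 ± 0.46, KRT5 at -2.06 ± 0.20 in renal and 7.29 ± 0.33 in genital cultures, and KRT14 near the upper limit of the arrays in the latter. The mucosal keratin KRT13 was lower at -7.67 ± 0.38, the envelope genes SPRR1B and SPRR1A at -8.42 ± 0.37 and -6.58 ± 0.57, and the serpin SERPINB5 at -7.78 ± 0.21. CRCT1, CSTA and S100A8, all near the floor in renal cultures, were lower at -7.45, -7.21 and -6.56, and the interferon-inducible IFI27 at -6.84 ± 0.97. IFI44, OAS1 and IFIT1 were lower at -2.30 ± 0.47, -2.14 ± 0.54 and -1.99 ± 0.64. Junction genes were split, with CLDN3 (near the floor in genital cultures) and EPCAM higher by 3.07 ± 0.23 and 1.84 ± 0.35 and the cadherins CDH1 and CDH3 lower at -2.41 ± 0.22 and -1.87 ± 0.22. Of mesenchymal markers, DCN, LUM, LOX, COL4A2 and COL6A3 were higher in renal cultures by 3.89 ± 0.67, 2.72 ± 0.76, 4.07 ± 0.59, 2.60 ± 0.58 and 2.52 ± 0.49, while FAP, TWIST2 and COL12A1 were lower at -3.14, -2.81 and -2.15. All 38 called genes, picked by size on these same arrays, lay on the stated side of the genital mean on 2 of 2 renal arrays.

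All 20 stratified epithelial genes were lower, also adjusted over the list alone, with a median of -6.24 (camera adjusted p 9.9e-43, estimated 7.95e-12). Proliferation genes were higher in 20 of 25, 23 adjusted over the list alone, with a median of 1.61 (2.12e-10, estimated p 0.378), and interferon genes lower in 9 of 16, 9 lower and 1 higher adjusted over the list alone, with a median of -0.997 (0.0253, estimated p 0.749). Renal tubule (2 of 6 higher, 1 lower), simple epithelial (3 of 23 higher, 7 lower, median -0.27 and mean 0.03 of opposite sign), collagen and matrix (8 of 29 higher, 2 lower) and fibroblast lists (2 of 15 higher, 3 lower, median -0.01 and mean 0.02) were not called. Set 1, which holds all these cultures, gave 2113 calls when fitted alone. The shared direction of all 2540 is by construction there and tests nothing. Without renal array 3 there were 1375 calls, where the lone renal array is assumed to vary like the other groups, and CA12, CDH6, COL12A1, IFIT1 and LUM lost their call without some single array.

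The mesenchymal cell types were then compared among themselves by an F-test over 22 types and 39 arrays, to read positional genes. It called 7919 of 9655 genes (82.0%), and 6731 (69.7%) with the array set in the model. The highest F values belonged to probes that follow the array sets: INSRR (F 154), HBB (116), SALL1 (109), LRRC38 (106), SECTM1 (96.5), PVALB (93.5), ZNF692 (92.1), RAI1 (87.2), METTL14 (77.9) and SERPINC1 (77.6). With the set in the model their F fell, for INSRR to 3.69, and HBB and RAI1 were no longer called (adjusted p 0.126 and 0.389). With the set, other genes had the highest F. The nicotinic receptor gene CHRNA3 (F 46.4) ranged from 2.98 in renal vein smooth muscle to -3.26 in cardiac stromal cultures, and TRPA1 (43.1) from 5.35 in ureter to -2.93 in hepatic vein smooth muscle. The semaphorin SEMA4D (37.8) was brightest in prostate stromal cells at 5.55, and the monooxygenase MOXD1 (35.4) in mammary stromal cells at 3.12. SRD5A2 (30.3) and TMCC3 (24.9) were brightest in pooled dermal fibroblasts, SOX17 (28.0) in pulmonary artery smooth muscle at 5.91 and the serpin SERPINB5 (27.2) in the ureter culture at 3.18. The nuclear receptor NR2C2 (25.8) and the phosphatase PPM1L (23.4) completed the 10.

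HOX genes carry the position of a tissue along the body, and 13 of 14 measured HOX genes differed among types (13 adjusted over the list alone), 12 with the array set in the model. The shares were 92.9% and 85.7%, against 82.0% and 69.7% of all genes (hypergeometric p 0.254 and 0.155). The first test decides nothing (even 14 of 14 cannot pass) and the second did not pass. HOXD1 was the exception (adjusted p 0.485), and HOXC4 lost its call with the set (0.113). HOXB4 (F 15.8) ranged from 1.50 in hepatic fibroblasts to -2.16 in popliteal vein smooth muscle, HOXB7 (12.1) from 1.89 in aortic smooth muscle to -2.81 in prostate stromal cells, and HOXD11 (7.91) from 2.56 in uterine to -2.66 in aortic smooth muscle. HOXC6, HOXD8, HOXB3, HOXB1, HOXD4, HOXC5 and HOXA2 had F values of 8.23, 7.08, 6.63, 5.49, 5.36, 5.23 and 5.15. Many of these types have a single array, which is assumed to vary like the replicated types.

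**Figure D4:**
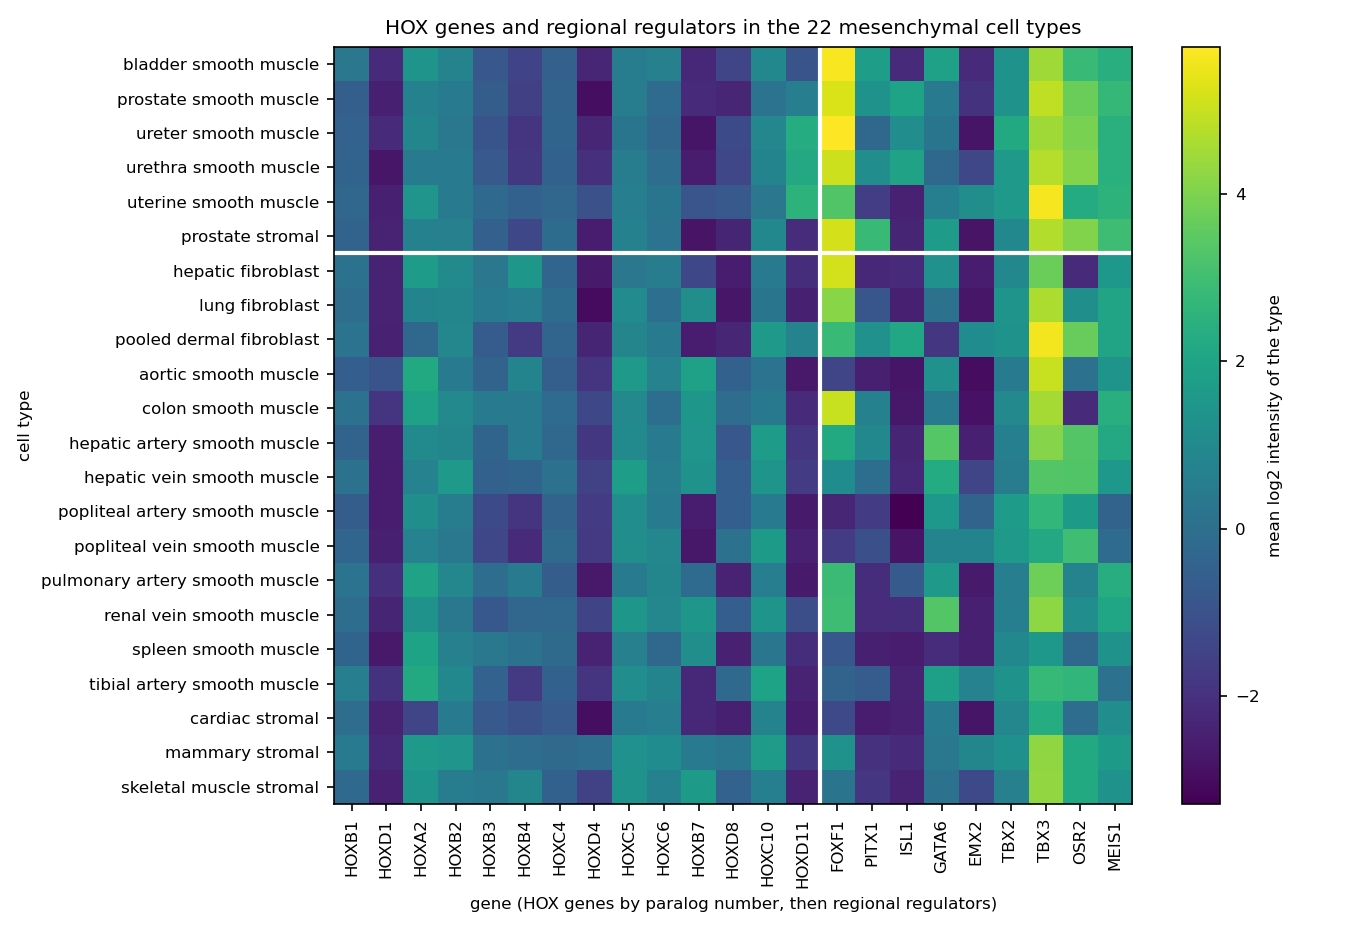
Mean log2 intensity (colour) of HOX genes and regional regulators (columns) in the 22 mesenchymal cell types (rows), with types of the urinary and genital tract above the white line. FOXF1 ranges from 5.75 in ureter to -2.30 in popliteal artery smooth muscle, and ISL1 reaches 2.13 in pooled dermal fibroblasts.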

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

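The tests of the array set on probes in 2 states, of RNA from other cells, of wrong labels and of the size of the rise were chosen only after the result was seen, while those of the other called genes and of the share of epithelial genes were chosen before.

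In the 3 cell types with 4 to 10 arrays, 27 measures were searched for an array whose gap to its nearest neighbour takes up most of the range of its type. Of 81 pairs of type and measure, 4 had such an array, and chance gives about 1 in 20. Pulmonary artery smooth muscle array 3 had a mean of 1.71 on the endothelial list, against -0.633 to 0.0441 on the other arrays of the type. Pulmonary artery smooth muscle array 2 had 0.0311 on the melanocyte and neural list, against -0.618 to -0.443. Iliac artery array 3 had 1.21 on HOX paralogs 6 to 8, against 1.34 to 1.36, and umbilical artery array 1 had -1.39 on HOX paralogs 9 to 13, against -1.01 to -0.786. A total of 4 in 81 is about the number that chance would give, so none of the 4 stands out by this search alone, and only the first was followed up on single genes.

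Endothelial transcripts on pulmonary artery smooth muscle array 3 may stem from RNA of endothelial cells in that culture, which stays open. Of 38 genes at least 4 log2 units higher in endothelial cultures, 34 (89.5%) were brighter than on every other array of the type, against at most 7.89% on another array and 20% by chance, with a median share of 21.7% of the endothelial level (quartiles 16.7 and 32.3), but the array was picked for such transcripts, so this count decides nothing. Abundant ones were IFI27 (5.06, others 1.77 ± 1.43), ESAM (4.43, others 0.60 ± 1.55), ECSCR (3.90, others 0.47 ± 0.96) and NMNAT1 (2.12, others -0.25 ± 1.93), while SOX17 was not raised (5.14) and is bright in this type anyway (6.10 ± 0.45). A raised background was argued against by 12 of 47 epithelial genes (25.5%) being brighter and by 76.3% of the 38 genes rising past the 95th percentile of the epithelial rises (1.17 in linear units), and a wrong label by a correlation that was higher by 0.0516 with its own type than with endothelial arrays. Uneven shares between genes, 4.55% for NMNAT1 and 42.4% for IFI27, leave open a difference of the culture itself, which was not tested, and no sort of the cells is given in the sources used here.

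Iliac artery endothelial array 1 carried mesenchymal transcripts, a pattern noticed beside the first that may stem from RNA of other cells, which stays open for the same reason. Of 38 genes at least 4 log2 units higher in mesenchymal cultures, 35 (92.1%) were brighter than on every other iliac array, against at most 5.26% on another and 25% by chance, with a median share of 2.99% (quartiles 1.08 and 6.07). COL1A2 lay at 2.88 (others -1.87 ± 0.29), COL6A3 at 2.24 (-0.24 ± 0.21), DCN at 2.14 (-1.46 ± 0.21) and AKR1C1 at 1.84 (1.02 ± 0.35), but MMP3 was not raised (0.26, others 0.58 ± 0.18). A wrong label was argued against by a correlation higher by 0.093 with its own type, and a raised background as the whole cause by 55.3% of the genes rising past the 95th percentile of the epithelial rises (0.306 in linear units), with a floor of 0.115 against 0.104 to 0.107. A small part of it stays open, since 38.3% of the epithelial genes (18 of 47) were brighter too, and a change of these endothelial cells towards a mesenchymal state was not tested.

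Genes called between arterial and microvascular endothelial cultures may in part follow the array set, which divides these classes completely. Among mesenchymal types, which the classes do not touch, 88.7% of 477 called genes not on probes in 2 states differed between set 2 and the other sets with the sign of the endothelial difference, above the 95th percentile of 80.5% under permuted set labels. The median ratio of the 2 differences was 0.528 (permuted 95th percentile 0.217). The 65 called genes on probes in 2 states all had the same sign (100%), which decides nothing. They were picked on the same mesenchymal arrays for not overlapping between sets 1 and 2, and permuted labels reached 100% too. A difference between vessel classes stays open for genes such as ALDH1A1, ADGRF5, PDE2A and KDR, whose set difference among mesenchymal types (-0.46, 0.06, 0.17 and 0.39) runs against the endothelial one, and it was not tested apart from the set.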

How the results depend on the processing

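Reading exact zeros as 0, the array set, array similarity within sets only (0.0361), the array floor and the removal of pulmonary artery smooth muscle array 3 with iliac array 1 were alternatives chosen after seeing the data, and the others were chosen before. Where no cause is given, the cause was not tested.

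All comparisons kept their count within 1.5 times under quantile normalization (3322, 2343, 111, 1, 872, 0, 558, 424 and 2811 genes, in the order of the report), and likewise under array centring, other pseudocounts, a model without trend and a robust model. The 0 of arterial against venous smooth muscle held in every alternative fit of all its sets, though 9 genes were called within set 1 alone, and the array similarity lay between 0.0252 and 0.362, without a change of sign. Of 287 named values, 285 kept direction and call under quantile normalization, and none reversed (0).

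Requiring at least 1 log2 unit leaves fewer genes by construction: 1137 for endothelial, 1184 for epithelial, 26 for smooth muscle against fibroblast, 234 for vascular, 192 for arterial against microvascular, 131 for iliac and 1235 for renal. The stricter dim-probe filter tests fewer genes and gave 2118 for endothelial, 1507 for epithelial, 269 for arterial against microvascular, 234 for iliac, 5110 in the F-test and 3 HOX genes. No filter gave 925 for arterial against microvascular. The mean of a gene's probes left 0 for stromal against fibroblast, where GALNT6 was lower at -2.56 with an adjusted p of 0.0583 in limma. Reading exact zeros as 0 kept 281 of 287 named values, turned GIMAP6 to -1.73 in the endothelial contrast and took the calls of MX1 (0.14, adjusted p 0.911), PDE2A, HOXA2 (epithelial) and HOXD11. In iliac cultures it made HOXA2 a called gene, lower at -4.16 ± 0.68 (adjusted p 0.000263), against the higher HOX list, through zeros on 3 of the 4 iliac arrays. Another probe stood for GIMAP6 and MX1 there, zero on 19.7% and 16.4% of the arrays, while PDE2A, HOXA2 and HOXD11 kept their probe.

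The title numbers as a block gave 249 for vascular, 119 for arterial against microvascular and 705 for iliac, and LPL turned to -0.0745. These numbers do not pair the arrays: deviations of same-number arrays of different types correlated at -0.00262 on average, against 0.000867 for different numbers, and 14 of 47 arrays had their best match at the same number. The array set as a term gave 2 for stromal and 176 for vascular, and turned PLN to 0.35 (smooth muscle against fibroblast), NOTCH4 to -0.035 and GJA4 to 0.15 (arterial against venous), none of them called before. It cannot be estimated for arterial against microvascular. The array floor as a covariate gave 2 for stromal, 471 for vascular, 1522 for arterial against microvascular and 264 for iliac, and turned PROX1 to -0.12.

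Treating arrays of a type as independent raised the counts to 1212 for smooth muscle against fibroblast, 653 for stromal, 1502 for vascular and 1818 for arterial against microvascular, since replicates then count as separate types. With 1 mean per type, and so fewer samples, 6, 0 and 15 remained for smooth muscle against fibroblast, stromal, and arterial against microvascular. All 61 arrays in the fit gave 15 for arterial against microvascular, and only the arrays compared gave 910 for renal. Without the pulmonary artery and iliac arrays above, iliac had 147 and DCN turned to -0.30, while the counts for endothelial (3289), epithelial (2318) and vascular (741) hardly moved.

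Leaving out 1 array or type at a time gave 2793 to 3577 for endothelial, 1457 (without the cervical type) to 2438 for epithelial, 3 (without pooled dermal fibroblasts) to 184 for smooth muscle against fibroblast, and 0 (without cardiac stromal, among others) to 7 for stromal. The range was 342 (without hepatic vein) to 1148 for vascular, 0 to 0 for arterial against venous, 110 (without umbilical) to 671 for arterial against microvascular, 130 (without iliac array 1) to 787 (without umbilical array 6) for iliac and 1375 (without renal array 3) to 3100 for renal. A lone array left in a group was assumed to vary like the other groups. No named called gene reversed (0), and other called genes were not followed. Named genes that had not passed did reverse. HOXD4 ranged from -0.27 to 1.88 (epithelial), DHCR7 from -0.70 to 0.16 (smooth muscle against fibroblast) and S100A4 from -0.81 to 2.66 (stromal). PDPN ranged from -1.16 to 0.20, UNC5B from -1.36 to 0.0431 and GJA4 from -0.41 to 0.0616 (arterial against venous). FABP4 ranged from -0.28 to 1.22, LPL from -0.22 to 1.33 and PROX1 from -0.45 to 0.82 (arterial against microvascular), and DCN from -0.30 to 0.98 (iliac).

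Signal over background limits the size of differences for genes whose dimmer group lies near the floor (0.0787 to 0.132), such as the 9 genes besides ALDH1A1 that rose most in arterial endothelial cultures. Of 1200 genes with further probes, the further probe had a median correlation of 0.336 with the one used, and 22% correlated below 0, so a value belongs to its probe.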

Other observations

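The test of HOX genes by body region was chosen only after the result was seen, and the splits of the samples were chosen before.

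Several regional transcription factors differed between cultures of one lineage, and the values below were chosen after they had been seen. FOXF1 lay at 5.65 ± 0.41 in bladder (3 arrays), 5.25 ± 0.33 in prostate (3 arrays), 5.75 in ureter, 4.98 ± 0.22 in colon and 5.06 ± 0.42 in urethra smooth muscle (2 arrays each), and also at 5.13 ± 0.64 in hepatic and 4.13 ± 0.13 in lung fibroblasts. It was dim in spleen (-0.83) and popliteal artery smooth muscle (-2.30). Among endothelial cultures FOXF1 lay at 3.43 ± 0.16 in uterine microvascular, against -0.07 ± 0.36 in umbilical and -1.88 ± 0.64 in iliac artery cells. ISL1 lay near 2 log2 units in cultures of different lineages: 1.97 ± 0.07 in vaginal and 1.93 ± 0.16 in cervical epithelium, 1.97 ± 0.51 in prostate and 1.93 ± 0.10 in urethra smooth muscle, and 2.13 ± 0.07 in pooled dermal fibroblasts, but it was dim in bladder (-2.21 ± 0.48) and uterine smooth muscle (-2.46 ± 0.35) and prostate stromal cells (-2.35). PITX1 was bright in vaginal (3.16 ± 0.68) and cervical epithelium (2.26 ± 0.29), prostate stromal cells (2.80) and bladder smooth muscle (1.77 ± 0.91) and dim in renal epithelium (-2.51 ± 0.05). EMX2 lay at 1.63 ± 0.31 in renal epithelium, 1.16 ± 0.90 in uterine smooth muscle and 1.09 ± 0.01 in pooled dermal fibroblasts. GATA6 was brightest in hepatic artery (3.36) and renal vein (3.34) smooth muscle and dim in spleen smooth muscle (-2.15) and pooled dermal fibroblasts (-1.85 ± 0.34).

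HOXB7 was bright in all endothelial types but 1, at 2.76 ± 0.22 in iliac, 2.54 ± 0.40 in umbilical, 2.70 ± 0.20 in saphenous vein, 3.11 ± 0.06 in uterine microvascular and 2.36 in bladder microvascular cells, but lay at -1.15 in the single cardiac microvascular array. Among other cultures HOXB7 was bright in renal epithelium (2.41 ± 0.13) and dim in bladder (-2.26 ± 0.39) and prostate smooth muscle (-2.21 ± 0.61). HOXD11 lay at 2.93 ± 0.67 in vaginal, 2.14 ± 0.72 in cervical and 2.36 ± 0.44 in renal epithelium and at 2.56 ± 1.13 in uterine smooth muscle. The 2 urethra arrays differed in HOXD11 (2.17 ± 2.70), as did the 3 bladder arrays (-0.92 ± 2.23).

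The mean of HOXD11 and HOXC10, the measured members of HOX paralogs 9 to 13, was 0.72 ± 0.92 in 6 mesenchymal types of the urinary and genital tract and -0.54 ± 0.64 in 16 others. The permutation p of 0.00234 for the difference of 1.26 decides nothing, since HOXD11 had been seen before the test. HOXD11 alone was higher by 2.79 in the tract and HOXC10 alone was lower at -0.27, so the mean does not describe both genes.

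Other splits of the samples were counted, with the real split included. Splits of arrays break up types, whose replicates are alike, so only splits of whole types can exclude chance. Chance can be excluded for endothelial against mesenchymal cultures, where 1 of 100 splits of the arrays called as many genes (real 3290, highest other 1) and 1 of 100 splits of whole cell types (highest other 386). The same holds for epithelial cultures (1 of 100 and 1 of 100, real 2328, highest others 93 and 1400), where the split that called 1400 kept the cervical and vaginal types together with renal vein smooth muscle. It also holds for vascular smooth muscle (1 of 100 and 1 of 100, real 802, highest others 6 and 316). For iliac against umbilical arteries only arrays could be split (1 of 100, real 413, highest other 103). Each side there is 1 type whose arrays may share a donor, so a chance difference between donors or cultures stays open. For smooth muscle against fibroblast chance was not excluded (2 of 100 and 5 of 100, real 89, highest others 505 and 140). For stromal against fibroblast it was not excluded (14 of 100 and 17 of 35, real 1, highest others 2 and 452). For arterial against venous smooth muscle the real count is 0, which every split reaches (100 of 100 and 56 of 56, highest other 349), so the splits say nothing about chance. That highest split sets the types of set 3 apart from the others, so it follows the array set, and with the set in the model the real comparison called 0. Splits that call 505, 452 or 349 genes point to a structure of the samples, traced for the last only. For arterial against microvascular endothelial cultures (1 of 100 over arrays, real 544, highest other 12) chance stays open. The 10 splits of whole types are too few for a share under 0.05 (1 of 10, highest other 330).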
